A study of Mus musculus with 620 samples.

How the data were processed

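Bulk RNA sequencing was carried out on mouse tissues, with 1 library per animal and tissue. Per the labels' protocols, tissue stored in RNAlater was homogenized, RNA was taken out with TRIzol or the RNAqueous kit, and poly(A) RNA was made into libraries with the NEBNext Ultra II kit, which does not mark strand. Per the submitters' processing notes, the genome build was GRCm39 and read quality was looked at with FastQC 0.11.9. The aligner, the counting tool and the annotation release were not given in the sources used here. The authors deposited 1 table of gene counts for each cohort. The LT table held whole-number counts of 24850 genes, and the ST and YA tables held estimated counts of 40840 genes, as deposited, of which 7.37% (ST) and 7.21% (YA) of the non-zero values were not whole. Those estimated counts were rounded to whole numbers for the tests. No table had a blank gene name, and the tables held the mitochondrial rRNA genes mt-Rnr1 and mt-Rnr2 but no protein-coding gene of mitochondrial DNA, for a reason not given in the sources used here, so the planned list of these genes could not be tested.

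Each library was given its condition, animal and tissue from its title and its sequencing batch from its description. For 2 LT exenatide livers, titled B13 and B14, the descriptions name these animals the other way round, so which liver came from which of the 2 is uncertain. Each animal appears in 1 condition. In LT, the liver was sequenced in batch 3 and white blood cells in batch 1, and the other tissues in batch 1 or 2 and batch 3, with all conditions in each batch. YA tissues were sequenced in batch 4, except colon in batch 6, and ST tissues in batch 5. Total counts per library had medians of 25.8 (LT), 26.2 (YA) and 24.8 M (ST). Where a gene had no counts in a group, no fold change is given.

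Counts were tested per tissue with edgeR 4.0.16 in R 4.3.3: TMM normalization, filterByExpr by condition, robust quasi-likelihood fits over all conditions of the cohort and tissue, and quasi-likelihood F tests, with batch as a covariate in LT tissues with 2 batches. P-values were adjusted by the Benjamini-Hochberg method within tissue and contrast, and a gene was called at an adjusted p under 0.05. Contrasts were aged against young controls and exenatide against aged controls (LT and ST), exenatide against controls (YA), rapamycin, knockdown, exenatide within knockdown, and the difference between the exenatide effects with and without knockdown (ST). CPM values are TMM-scaled. Lists of genes, 48 in number and with at least 5 tested members, were tested with fry (limma 3.58.1), adjusted over all lists and tissues of a contrast; camera with an estimated correlation was run beside it. The lists called in no contrast and tissue were alveolar and airway epithelium (smallest adjusted p = 0.0685), hypothalamic neuropeptides (0.0510) and testis and epididymis contamination (0.298).

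Contrasts, tests, lists, alternatives and the naming rule were fixed before the data were examined. Lists to describe were chosen after results were seen. The rule took, per contrast, up to 8 genes called in the same direction in the most tissues (at least 2), the called gene with the largest rise and the largest fall in each tissue with 10 or more calls (average log2 CPM of at least 1), up to 4 members with the smallest adjusted p of each list described, and Glp1r. Predicted and clone names and immunoglobulin or T cell receptor segments were left out of the first 2 parts. Genes from outside the rule are said to have been chosen after their values were seen.

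Scores were the mean over signature genes of the signed log2 CPM (prior count 2), where a signature held the genes called in another cohort in the same tissue (at least 20). Differences were tested by two-sided exact permutation, or with 100000 resamples where there were more arrangements, within batches in LT. Correlations across genes were set beside 20 simulated pairs of unchanged groups and beside 20 splits of the shared controls. Genes of the simulated pairs varied independently of each other, unlike real genes. The steps were tested on simulated counts. At 2-fold, edgeR recovered 94.9% of the changed genes in LT heart (14903 genes tested), 90.6% in YA colon (17131) and 77.8% in ST hippocampus (18404), and at 4-fold 100%, 100% and 99%. In simulated ST hippocampus data with 18586 genes, fry called 2 of 20 lists without and 20 of 20 lists with a shift of 0.5, and camera 0 and 20. The permutation test with n = 5 per group passed in 6% of 200 simulations without a difference and in 97.5% with 1 of 3 SD.

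Alternatives were DESeq2's size factors in edgeR, no filter on low counts, DESeq2 1.42.0 (Wald test), fits limited to the conditions compared, each animal left out in turn and, in LT, no batch term, batch 3 alone and batches 1 and 2 alone. After the data were seen, 3 more were added: each library's trend on transcript length and GC content removed as an offset (natural splines with 4 degrees of freedom each), libraries left out whose median correlation with the others of their tissue lay over 5 median absolute deviations low (12 of 284 in LT, 7 of 128 in YA and 14 of 208 in ST), and 2 young colon libraries left out. Lengths and GC content came from an annotation of an older mouse build, matched by gene symbol for 88.6% to 94.4% of the tested genes, and no coordinates are given. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.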

Results

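RNA was measured in 620 tissue libraries from 72 mice, and each animal belonged to 1 of 11 conditions in 3 cohorts, which the labels call LT, YA and ST. The conditions separate age, treatment with exenatide (a peptide agonist of the glucagon-like peptide-1 receptor, GLP-1R), treatment with rapamycin (an inhibitor of the mTOR kinase) and knockdown of GLP-1R in the hypothalamus. Doses, ages in months and lengths of treatment were not given in the sources used here. The LT cohort held 284 libraries of 12 tissues from 8 young controls, 9 aged controls and 8 aged exenatide-treated mice. White blood cells had n = 5 in each LT group, young colon and young skeletal muscle had n = 6, and frontal cortex and lung had n = 8 aged controls. The YA cohort held 128 libraries of 8 tissues from 8 control and 8 exenatide-treated animals. The ST cohort held 208 libraries of 7 tissues from 6 conditions: young controls, aged controls, and aged mice given exenatide, rapamycin, the knockdown, or exenatide with the knockdown. Each ST group had n = 5 in each tissue, except white blood cells after exenatide and after rapamycin (n = 4). Young ST controls came from 6 animals, of which 5 were sequenced in each tissue. Total counts ran from 15.2 to 33.8 M per library in LT (median 25.8), from 15 to 34.1 M in YA (median 26.2) and from 14.6 to 56.2 M in ST (median 24.8).

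Gene values below are log2 fold changes ± standard errors, with Benjamini-Hochberg adjusted p-values from edgeR's quasi-likelihood test within each tissue. "Rose", "fell" and "changed" are used for adjusted p under 0.05. Gene lists were tested with fry, which asks whether the members of a list move one way on balance and does not compare the list with other genes. Members were also counted after adjustment over the list alone. Genes with near-identical copies in the genome (C4b, Csprs, Cyp2a4, Cyp2b9, Hsd3b5, Mup7, Mup15, Gvin-ps6, Pisd-ps3, the Nat8f, haemoglobin, H2 and immunoglobulin genes, and single ribosomal proteins with processed copies) are uncertain, because how shared reads were counted was not given in the sources used here. So is Zbed6, which lies inside another gene.

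In the LT cohort, aged and young controls were compared to ask how age changed each tissue. Adipose tissue of aged mice carried far more immune transcripts than that of young mice (n = 9 and 8). Of the B and plasma cell markers, 18 rose and 0 fell of 19 tested (18 and 0 adjusted over the list alone, fry's adjusted p = 9.55e-06, adjusted p = 0.395 with an estimated correlation), led by Igkc (5.41 ± 0.62), an immunoglobulin light chain, and Jchain (4.57 ± 0.53), which joins polymeric antibodies. Of the macrophage markers, 14 rose and 0 fell of 17 tested (14 and 0 adjusted over the list alone, fry's adjusted p = 4.07e-04, adjusted p = 0.531 with an estimated correlation). Gpnmb, a glycoprotein of lipid-laden macrophages, rose by 3.85 ± 0.51, from 43.5 ± 27.8 (SD, n = 8) to 646 ± 414 (SD, n = 9) CPM, and the macrophage receptors Trem2 (1.98 ± 0.29) and Adgre1 (2.19 ± 0.36) rose with it. T and NK cell markers moved the same way (16 rose and 0 fell of 19 tested, 16 and 0 adjusted over the list alone, fry's adjusted p = 0.0018, adjusted p = 0.611 with an estimated correlation), including Cd4 (3.05 ± 0.51), Cd8a (2.72 ± 0.49) and the granzyme Gzmk (3.92 ± 0.71). Lymph node and germinal centre genes rose in the same samples (7 rose and 0 fell of 8 tested, 7 and 1 adjusted over the list alone, fry's adjusted p = 0.00124, adjusted p = 0.57 with an estimated correlation), including the complement receptor Cr2 (4.41 ± 0.86) and Cxcl13 (4.06 ± 0.82), and how much lymph node the dissected fat held was not measured. Among complement genes 13 rose and 0 fell of 15 tested (13 and 0 adjusted over the list alone, fry's adjusted p = 7.49e-04, adjusted p = 0.57 with an estimated correlation), with C3 (1.59 ± 0.24) among them. Without A52, Cd8a, Cr2 and Cxcl13 were at 3.304, 5.144 and 5.09. The largest adjusted p among these genes was 4.22e-04.

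The transcripts of fat cells and vessels were lower in aged LT adipose tissue. Of the white adipocyte genes, 0 rose and 14 fell of 17 tested (0 and 14 adjusted over the list alone, fry's adjusted p = 0.00335, adjusted p = 0.57 with an estimated correlation), among them the lipase Lipe (-1.43 ± 0.25) and adiponectin (Adipoq, -1.18 ± 0.23). The nuclear-encoded oxidative phosphorylation genes fell almost throughout: 0 rose and 35 fell of 38 tested (0 and 36 adjusted over the list alone, fry's adjusted p = 0.00409, adjusted p = 0.611 with an estimated correlation), with Ndufa4 at -0.98 ± 0.16 and Atp5o at -0.88 ± 0.16. For endothelial genes 0 rose and 12 fell of 12 tested (0 and 12 adjusted over the list alone, fry's adjusted p = 0.00103, adjusted p = 0.554 with an estimated correlation), as shown by Egfl7 (-1.31 ± 0.20), Emcn (-1.25 ± 0.20) and Tie1 (-1.18 ± 0.22). Smooth muscle genes fell too (0 rose and 9 fell of 11 tested, 0 and 9 adjusted over the list alone, fry's adjusted p = 3.28e-04, adjusted p = 0.464 with an estimated correlation), such as Tagln (-1.58 ± 0.25) and Myh11 (-1.42 ± 0.25). Fatty acid synthesis genes followed (0 rose and 12 fell of 17 tested, 0 and 12 adjusted over the list alone, fry's adjusted p = 0.0186, adjusted p = 0.63 with an estimated correlation), including the citrate carrier Slc25a1 (-1.91 ± 0.41). The amino acid transporter Slc38a5 fell too (-6.07 ± 1.15; -4.942 without A58 and -7.482 without B39). For these genes adjusted p was at most 6.89e-04.

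The kidney and heart of aged LT mice also gained immune transcripts. In the kidney, Jchain rose by 4.30 ± 0.40, from 15.9 ± 5.89 (SD, n = 8) to 315 ± 155 (SD, n = 9) CPM. Of the kidney's B and plasma cell markers 13 rose and 0 fell of 15 tested (13 and 0 adjusted over the list alone, fry's adjusted p = 9.55e-06, adjusted p = 0.239 with an estimated correlation). The complement gene C4b rose in kidney by 2.49 ± 0.25, and within the complement list 9 rose and 0 fell of 15 tested (10 and 0 adjusted over the list alone, fry's adjusted p = 4.31e-04, adjusted p = 0.317 with an estimated correlation). Of the kidney macrophage markers 14 rose and 0 fell of 16 tested (14 and 0 adjusted over the list alone, fry's adjusted p = 4.31e-04, adjusted p = 0.317 with an estimated correlation), including Lyz2 (1.95 ± 0.27) and Trem2 (2.39 ± 0.41). The tubule injury gene Havcr1 (kidney injury molecule 1) rose by 2.49 ± 0.40, Krt20 by 4.08 ± 0.44 and the adhesion molecule Vcam1 by 1.80 ± 0.19. For the list kidney tubule and injury, 4 rose and 1 fell of 16 tested (4 and 3 adjusted over the list alone, fry's adjusted p = 0.0115, adjusted p = 0.554 with an estimated correlation), where fry's direction was up and the median of the list was -0.10. In the heart, the B cell chemokine Cxcl13 rose by 4.39 ± 0.53, the T cell genes Cxcr6 by 2.17 ± 0.36 and Ccl5 by 2.60 ± 0.48, the cell cycle inhibitor Cdkn2a by 1.99 ± 0.43 and C4b by 1.61 ± 0.28, while the decarboxylase Ddc fell (-2.49 ± 0.28). Of the heart's MHC class I presentation genes 12 rose and 0 fell of 16 tested (15 and 0 adjusted over the list alone, fry's adjusted p = 0.00827, adjusted p = 0.499 with an estimated correlation). Adjusted p was 0.00264 or lower for each of these genes.

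In the aged LT brain, C4b rose in frontal cortex (1.19 ± 0.19) and hypothalamus (1.14 ± 0.22), and the lipid droplet gene Plin4 rose in frontal cortex (2.33 ± 0.37) and hippocampus (2.69 ± 0.41). MHC class I genes rose in frontal cortex (9 rose and 0 fell of 15 tested, 10 and 0 adjusted over the list alone, fry's adjusted p = 0.00377, adjusted p = 0.395 with an estimated correlation), B2m by 0.58 ± 0.09. Cell proliferation genes fell there (0 rose and 6 fell of 22 tested, 0 and 8 adjusted over the list alone, fry's adjusted p = 4.99e-04, adjusted p = 0.371 with an estimated correlation), with Top2a at -1.83 ± 0.26 and Mki67 at -1.005 ± 0.19. In the hypothalamus, oligodendrocyte and myelin genes fell (0 rose and 9 fell of 18 tested, 0 and 11 adjusted over the list alone, fry's adjusted p = 0.023, adjusted p = 0.554 with an estimated correlation), among them the myelin genes Mog (-0.52 ± 0.10) and Opalin (-0.84 ± 0.17) and, outside the list, Enpp6 (-1.25 ± 0.24). Aged lung held more platelet and megakaryocyte transcripts (10 rose and 0 fell of 10 tested, 10 and 0 adjusted over the list alone, fry's adjusted p = 3.28e-04, adjusted p = 0.317 with an estimated correlation), such as Ppbp (1.59 ± 0.25). Lung extracellular matrix genes fell (0 rose and 14 fell of 26 tested, 0 and 17 adjusted over the list alone, fry's adjusted p = 0.00456, adjusted p = 0.395 with an estimated correlation), including Col1a2 (-1.12 ± 0.19) and Col6a2 (-0.74 ± 0.12). Platelet genes also rose in aged white blood cells (n = 5 and 5; 10 rose and 0 fell of 10 tested, 10 and 0 adjusted over the list alone, fry's adjusted p = 0.0163, adjusted p = 0.57 with an estimated correlation). MHC class II genes fell there (0 rose and 8 fell of 8 tested, 0 and 8 adjusted over the list alone, fry's adjusted p = 0.00456, adjusted p = 0.531 with an estimated correlation), with H2-Ab1 at -0.83 ± 0.18. In spleen, Xbp1, a transcription factor of secretory cells, rose by 1.01 ± 0.10 as unfolded protein and integrated stress response genes rose (14 rose and 0 fell of 24 tested, 17 and 0 adjusted over the list alone, fry's adjusted p = 3.87e-04, adjusted p = 0.371 with an estimated correlation). Among the genes above, adjusted p reached at most 0.00679.

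Several genes moved with age across LT tissues. Csprs rose in adipose tissue (6.36 ± 0.45), heart (2.91 ± 0.33), kidney (2.13 ± 0.45), liver (2.49 ± 0.36), lung (3.28 ± 0.38) and spleen (1.16 ± 0.20). Nrep fell in adipose tissue (-1.80 ± 0.34), skeletal muscle (-1.38 ± 0.20), lung (-0.98 ± 0.18), heart (-0.85 ± 0.18) and frontal cortex (-0.72 ± 0.08). The chemokine Ccl8 rose in adipose tissue (2.92 ± 0.52), liver (3.44 ± 0.71; 4.267 without A52) and spleen (2.44 ± 0.50). Other single genes that changed were Ppp2r2c (3.51 ± 0.18) and Phex (-2.41 ± 0.26) in lung, Cacna1i, a calcium channel, in muscle (3.09 ± 0.40) and Nid1, a basement membrane gene, in white blood cells (-2.05 ± 0.18). In muscle, the atrophy gene Fbxo32 rose by 1.02 ± 0.19 (4 rose and 0 fell of 15 tested, 5 and 0 adjusted over the list alone, fry's adjusted p = 0.016, adjusted p = 0.531 with an estimated correlation of the list denervation and atrophy of muscle). The largest adjusted p among these genes was 0.00543.

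Summed over the 12 LT tissues, 26891 gene tests passed for age, 13885 up and 13006 down (51.6% up), with 14778 to 18007 genes tested per tissue. Adipose tissue gave 8551 of them, heart 2696 and kidney 1216. Counts in 9 other tissues moved by over 1.5 times with 1 or more animals left out, as the plot of calls per tissue shows. Within batches the sum was 18621 in batches 1 and 2 and 3509 in batch 3, which holds 3 or 4 libraries in most groups. With DESeq2's Wald test it was 33206. Of the 496 lists tested for age, fry called 126 (99 up and 27 down) and camera with an estimated correlation called 0 (50 at an unadjusted p under 0.05).

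**Figure D1:**
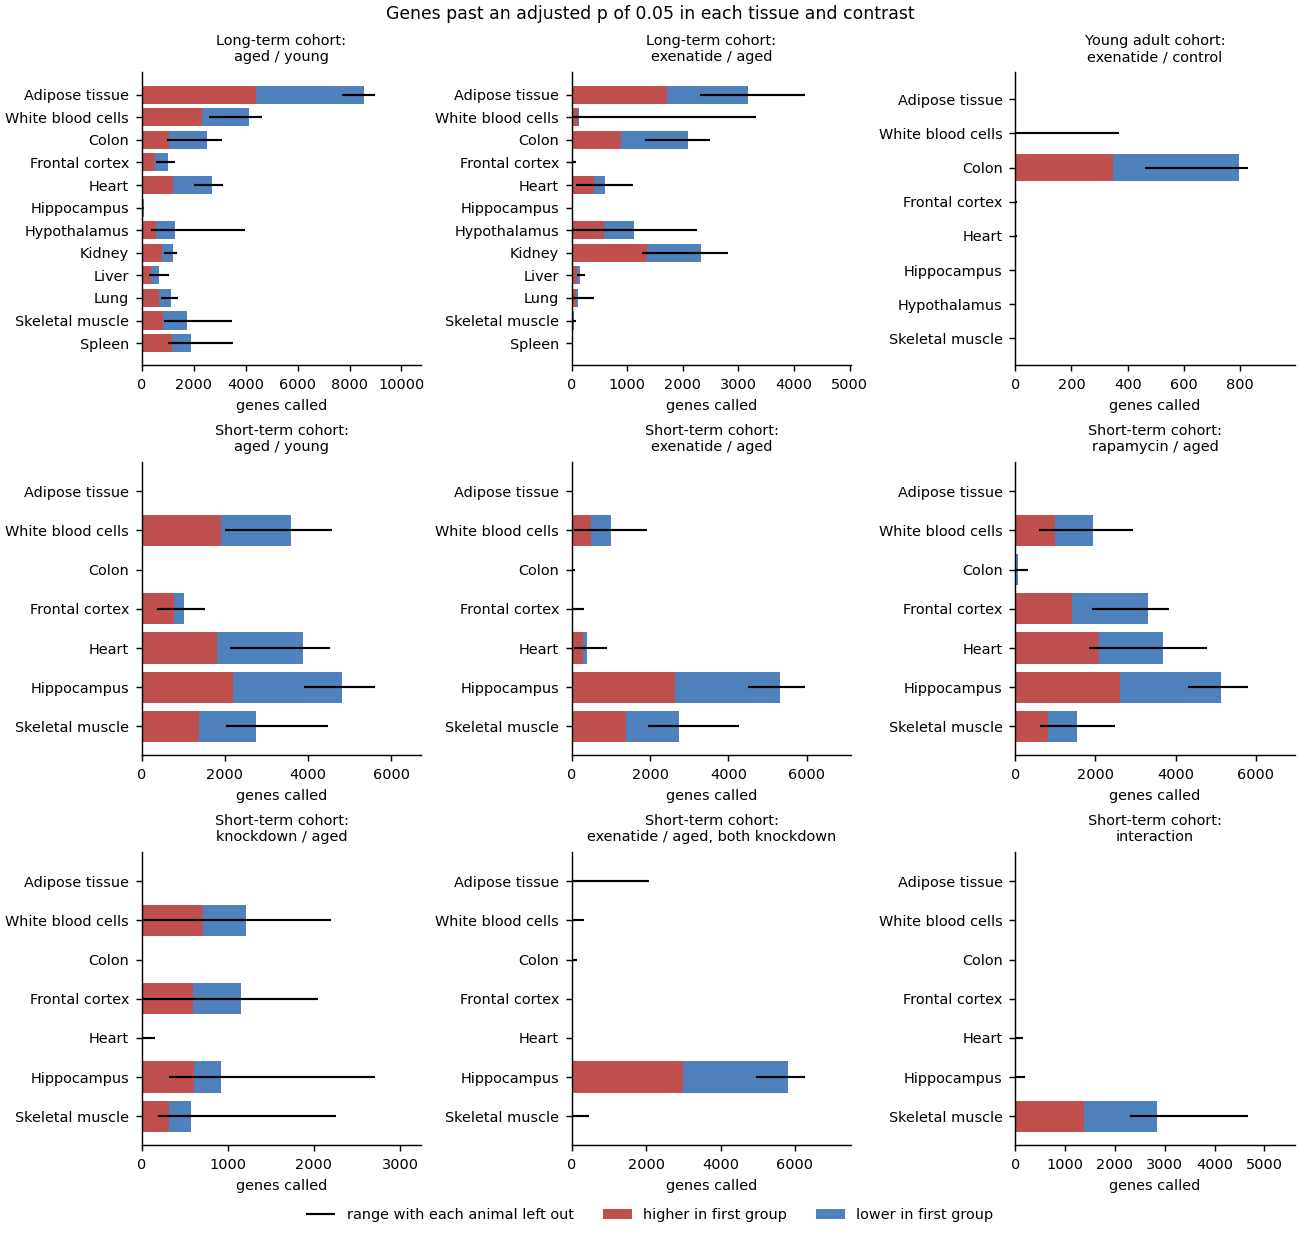
Numbers of genes with adjusted p under 0.05 per tissue in each of the 9 comparisons, higher in the first group named (red) or lower (blue). Black lines give the range of the total with each animal left out in turn; LT age in adipose tissue ran from 7694 to 8964 around 8551, and ST knockdown in white blood cells from 18 to 2199 around 1211.

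Aged LT mice given exenatide were compared with aged LT controls to ask what the drug changed. In the kidney (n = 8 and 9), smooth muscle genes rose (8 rose and 0 fell of 10 tested, 9 and 0 adjusted over the list alone, fry's adjusted p = 0.00229, adjusted p = 0.671 with an estimated correlation), including Acta2 (0.93 ± 0.15), Tagln (1.01 ± 0.18) and Myh11 (0.68 ± 0.13). Endothelial genes rose in the same kidneys (9 rose and 0 fell of 12 tested, 9 and 0 adjusted over the list alone, fry's adjusted p = 0.00229, adjusted p = 0.671 with an estimated correlation), with Tie1 at 0.57 ± 0.08, Cdh5 at 0.62 ± 0.12 and Pecam1 at 0.46 ± 0.10. Ednrb, the endothelin B receptor, rose in kidney (1.25 ± 0.21) and in liver (1.37 ± 0.20). Erythroid transcripts moved with the exenatide kidneys (5 rose and 0 fell of 8 tested, 5 and 0 adjusted over the list alone, fry's adjusted p = 0.0251, adjusted p = 0.671 with an estimated correlation). Hbb-bt rose by 2.94 ± 0.53, from 1.48 ± 1.08 (SD, n = 9) to 10.3 ± 6.41 (SD, n = 8) CPM, and Alas2, the first enzyme of haem synthesis in red cells, by 2.78 ± 0.59. Of the kidney's extracellular matrix genes 11 rose and 0 fell of 26 tested (15 and 0 adjusted over the list alone, fry's adjusted p = 0.129), with the collagen IV chain Col4a2 at 0.40 ± 0.08 and Loxl1, which cross-links elastin, at 1.02 ± 0.25. For these genes adjusted p was at most 0.0114. With the trend on transcript length and GC content removed, the calls of Col4a2 (kidney) and Loxl1 (kidney) were lost.

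In adipose tissue of exenatide-treated LT mice, some genes of fat cells rose, but no list passed fry's test in this tissue, and another split of the LT animals gave 4122 calls in it, against the real 3174. Of the white adipocyte genes 7 rose and 0 fell of 17 tested (8 and 1 adjusted over the list alone, fry's adjusted p = 0.41), among them complement factor D (Cfd, 1.67 ± 0.32) and Lipe (1.07 ± 0.25). Of the fatty acid synthesis genes 9 rose and 0 fell of 17 tested (11 and 0 adjusted over the list alone, fry's adjusted p = 0.209), with Slc25a1 at 1.81 ± 0.40 and the acetyl-CoA carboxylase Acaca at 1.65 ± 0.41. Of the genes of oxidative phosphorylation, nuclear-encoded, 21 rose and 0 fell of 38 tested (29 and 0 adjusted over the list alone, fry's adjusted p = 0.116), for example Ndufa2 (1.12 ± 0.21) and Cox5b (0.99 ± 0.20). The erythroid markers rose here as well (5 rose and 0 fell of 5 tested, 5 and 0 adjusted over the list alone, fry's adjusted p = 0.0551), Hbb-bt by 1.88 ± 0.49, and the adaptor Trip10 rose by 0.81 ± 0.14. Adjusted p was 0.0103 or lower for each of these genes.

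In the LT colon, exenatide lowered the mast cell protease Cma2 (-4.84 ± 0.90) and the co-chaperone Fkbp4 (-0.64 ± 0.11). Unfolded protein and integrated stress response genes fell in colon (0 rose and 11 fell of 24 tested, 0 and 12 adjusted over the list alone, fry's adjusted p = 0.0369, adjusted p = 0.869 with an estimated correlation), including the transcription factor Atf4 (-1.05 ± 0.21), its target Chac1 (-2.37 ± 0.48) and Dnajb11 (-0.56 ± 0.12). In the liver (n = 8 and 9), the steroid hydroxylase Cyp2a4 rose by 6.08 ± 1.17, from 3.72 ± 6.36 (SD, n = 9) to 250 ± 349 (SD, n = 8) CPM, and Mup15, a major urinary protein gene, fell by 6.97 ± 1.11. Without B36 the second Cyp2a4 mean was 135 CPM and the log2 fold change 5.22, and without B24 the first mean was 1.68 CPM and the log2 fold change 7.201. Liver genes chosen after their values were seen moved with them: Cux2 (5.46 ± 0.58) and Cyp2b9 (4.41 ± 0.86) rose and Mup7 (-5.35 ± 0.98) and Hsd3b5 (-3.33 ± 0.69) fell. Other values that moved by over 1.5-fold without 1 animal were Cma2 (-3.997 without B27), Chac1 (-3.034 without B13), Mup15 (-9.232 without B26), Cux2 (6.085 without B39), Cyp2b9 (5.556 without B41) and Mup7 (-6.448 without B25). Among the genes above, adjusted p reached at most 0.0162. With the trend on transcript length and GC content removed, the call of Chac1 (colon) was lost. With the fit limited to the 2 conditions compared, the call of Hsd3b5 (liver) was lost.

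Over the LT tissues, 9754 gene tests passed for exenatide, 5218 up and 4536 down, in 11 of 12 tissues, and the sum was 6266 with animal B14 left out. Adipose tissue gave 3174, and each of the other tissues with calls moved by over 1.5 times with 1 or more animals left out. Hippocampus gave 0 with edgeR (1290 at an unadjusted p under 0.05) and 13 with DESeq2; spleen gave 1, Myo18b (1.46 ± 0.22), named after its value was seen, which was not called with only the conditions compared. The sum was 7771 within batches 1 and 2 and 3310 within batch 3, 3295 with the trend on transcript length and GC content removed, and 15582 with DESeq2. Among the 105 calls of named genes, not all of them printed here, 57 were kept and 48 lost with that trend removed. With batch 3 alone, 25 of 101 named calls were kept. Of the 496 lists tested, fry called 13 (5 up and 8 down) and camera with an estimated correlation 0 (29 at an unadjusted p under 0.05).

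**Figure D2:**
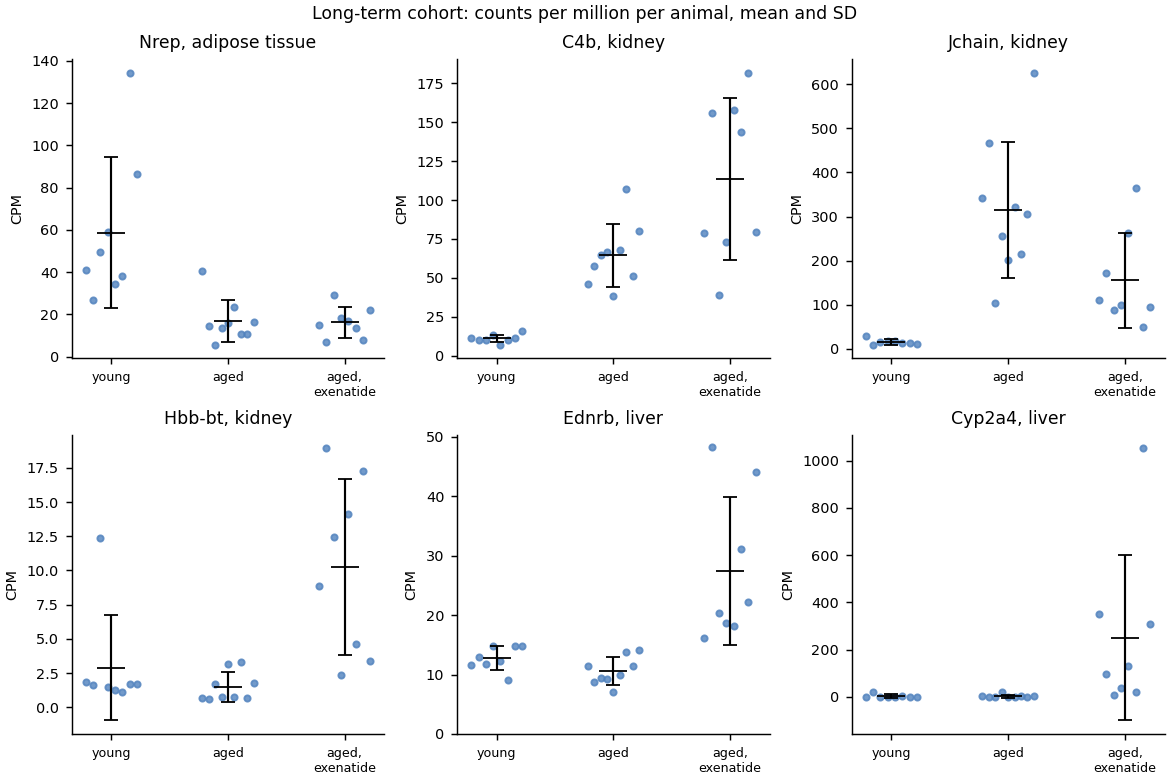
CPM of 6 genes in LT tissues, 1 point per animal with the group mean and SD, for young controls, aged controls and aged exenatide-treated mice. Mean kidney Jchain was 15.9, 315 and 155 CPM and mean kidney C4b 11.1, 64.4 and 114 CPM in that order, while liver Ednrb was 12.8, 10.6 and 27.4 CPM.

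Age and exenatide effects of the LT cohort were set against each other to ask whether the drug moved the genes that age moved. Across genes, which are not independent replicates, Pearson's r between the log2 fold changes had a median of -0.29 over 12 tissues, from -0.56 in hypothalamus to 0.02 in liver. Both effects use the aged controls with opposite sign, and simulated groups without any effect gave a median of -0.47. With the aged controls split into 2 groups the median was -0.12, below 0 in 10 tissues and above 0 in 2. In adipose tissue r was -0.51 (-0.41 with split controls) and the covariance was -0.21, against -0.04 in simulated groups without effects. In heart r was -0.24 (-0.05 split) and in liver 0.02 (0.13 split). Genes called in both contrasts moved in opposite directions 3870 times (1155 for independent lists of these sizes, n1 × n2 / N), both up 79 times (637) and both down 43 times (537). Neither reference accounts for shared controls and effects together, so the excess is not a count of shared effects.

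In the YA cohort, exenatide and control animals (n = 8 and 8) differed in the colon. The bile acid transporter Slc10a2 rose by 1.87 ± 0.27 and the lipase Pnliprp2 fell (-3.85 ± 0.63). Itln1, a lectin secreted in the gut, fell (-2.88 ± 0.50) and was named after its value was seen. Of the list colon epithelium 2 rose and 4 fell of 21 tested (2 and 5 adjusted over the list alone, fry's adjusted p = 0.85), the falls including Clca1 (-1.70 ± 0.36) and the rises Slc26a3 (0.79 ± 0.10) and Car1 (1.49 ± 0.29). Of the unfolded protein and integrated stress response genes 0 rose and 12 fell of 24 tested (0 and 17 adjusted over the list alone, fry's adjusted p = 0.146), with Asns at -0.60 ± 0.10 and Dnajb9 at -0.52 ± 0.10. Of the B and plasma cell markers 0 rose and 4 fell of 19 tested (0 and 10 adjusted over the list alone, fry's adjusted p = 0.406), Jchain at -1.75 ± 0.40. The colon gave 796 calls (347 up and 449 down), 461 without animal A87 and 496 without A38, and DESeq2 called 1449 over all tissues. Heart gave 2 calls, Dnajb5 (-0.51 ± 0.08) and Hr (0.57 ± 0.09), named after their values were seen. It gave 0 without any of A32, A33, A34, A38, A80, A81, A82, A83, A84 or A87, 1 without A31 or A88, 4 without A41 and 5 without A37, and DESeq2 gave 21. Hr was also not called without A79. Adipose tissue, white blood cells, frontal cortex, hippocampus, hypothalamus and muscle gave 0 with edgeR, against 448, 3398, 2091, 266, 701 and 768 at an unadjusted p under 0.05 and 0, 4, 52, 6, 2 and 31 with DESeq2, in that order. Fry called 0 of 317 lists (27 at an unadjusted p under 0.05; camera 0). The largest adjusted p among these genes was 0.0434. With the trend on transcript length and GC content removed, the call of Hr (heart) was lost.

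In the ST cohort, aged and young controls (n = 5 and 5) differed in glia and immune genes of the brain and heart. In hippocampus C4b rose by 1.90 ± 0.26 and the microglial receptor Clec7a by 2.73 ± 0.46, as they did in frontal cortex (1.67 ± 0.22 and 2.11 ± 0.33). Homeostatic microglia genes rose in hippocampus (10 rose and 0 fell of 12 tested, 11 and 0 adjusted over the list alone, fry's adjusted p = 9.58e-04, adjusted p = 0.651 with an estimated correlation), including P2ry12 (0.38 ± 0.08). Interferon response genes rose there too (22 rose and 0 fell of 31 tested, 24 and 0 adjusted over the list alone, fry's adjusted p = 0.0314, adjusted p = 0.681 with an estimated correlation), Oas2 by 1.64 ± 0.30 and Parp14 by 1.18 ± 0.20, and the antiviral gene Zc3hav1 rose by 1.04 ± 0.11. The hippocampal genes of oxidative phosphorylation, nuclear-encoded, fell (0 rose and 29 fell of 38 tested, 0 and 32 adjusted over the list alone, fry's adjusted p = 6.67e-06, adjusted p = 0.651 with an estimated correlation), with Cox5b at -1.27 ± 0.12 and Ndufa2 at -1.01 ± 0.09. So did cytosolic ribosomal proteins (0 rose and 33 fell of 40 tested, 1 and 34 adjusted over the list alone, fry's adjusted p = 6.67e-06, adjusted p = 0.651 with an estimated correlation), with Rps29 at -1.26 ± 0.11 and Rpl23 at -0.76 ± 0.07. Excitatory and inhibitory neuron genes fell as well (0 rose and 7 fell of 16 tested, 0 and 8 adjusted over the list alone, fry's adjusted p = 0.0115, adjusted p = 0.651 with an estimated correlation), with Nrgn at -0.66 ± 0.08 and Rbfox3 at -0.59 ± 0.09. The choroid plexus gene Ttr fell by 4.996 ± 1.24, from 2790 ± 4710 (SD, n = 5) to 87.6 ± 133 (SD, n = 5) CPM (adjusted p = 0.00425), but not with the fit limited to the 2 conditions compared. Without A47 the young mean was 749 CPM and the log2 fold change -3.104 (adjusted p = 0.0326), and without E30 the aged mean was 28.5 CPM and the log2 fold change -6.611. For the other genes adjusted p was at most 4.72e-04.

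The heart of aged ST mice gained macrophage markers (16 rose and 0 fell of 17 tested, 16 and 0 adjusted over the list alone, fry's adjusted p = 0.00952, adjusted p = 0.651 with an estimated correlation), such as Adgre1 (1.498 ± 0.30), Ctss (1.81 ± 0.39) and Gpnmb (1.67 ± 0.26). Heart complement genes rose (13 rose and 0 fell of 14 tested, 14 and 0 adjusted over the list alone, fry's adjusted p = 0.0139, adjusted p = 0.651 with an estimated correlation), such as C4b (1.91 ± 0.39) and C1s1 (1.15 ± 0.21). Cxcl13 rose by 4.26 ± 1.18. In skeletal muscle endothelial genes rose (11 rose and 0 fell of 12 tested, 11 and 0 adjusted over the list alone, fry's adjusted p = 0.00507, adjusted p = 0.651 with an estimated correlation), Kdr by 1.51 ± 0.30 and Vwf by 2.01 ± 0.41, and the transcription factor Zbed6 fell (-3.77 ± 0.53). In white blood cells the antimicrobial peptide gene Camp rose by 6.51 ± 1.64 and Gvin-ps6 fell (-3.87 ± 0.61); Camp was at 7.179 without A43 and 5.003 without E23, and Gvin-ps6 at -4.674 without E32. Pisd-ps3 rose in frontal cortex (1.61 ± 0.31), heart (0.49 ± 0.10), hippocampus (1.31 ± 0.32) and muscle (1.02 ± 0.22). Adjusted p was 0.0137 or lower for each of these genes. Over 7 tissues 16066 gene tests passed, 8085 up and 7981 down, of which hippocampus gave 4826; counts of the other tissues moved by over 1.5 times with 1 or more animals left out. Adipose tissue gave 0 with edgeR (1033 at an unadjusted p under 0.05) and 62 with DESeq2, and colon gave 4, Rps4l (-2.62 ± 0.33), Nat8f7 (3.26 ± 0.48), Nat8f2 (1.84 ± 0.30) and Nat8f3 (2.08 ± 0.35), named after their values were seen. Colon gave 2 calls without A46 (neither Nat8f2 nor Nat8f3), 8 without A42, A43 or A44, and 10 without A47. Nat8f3 was also no longer called without E29 (adjusted p = 0.0647). With only the conditions compared in the model, Nat8f2 and Nat8f3 were no longer called. Fry called 32 of 295 lists (22 up and 10 down) and camera with an estimated correlation 0 (15 at an unadjusted p under 0.05).

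Exenatide in aged ST mice was compared with aged ST controls (n = 5 and 5, white blood cells 4 and 5). In hippocampus cytosolic ribosomal proteins rose (35 rose and 0 fell of 40 tested, 36 and 0 adjusted over the list alone, fry's adjusted p = 6.01e-07, adjusted p = 0.903 with an estimated correlation), Rps29 by 1.36 ± 0.11 and Rpl38 by 1.30 ± 0.11. Genes of oxidative phosphorylation, nuclear-encoded, rose with them (31 rose and 0 fell of 38 tested, 32 and 0 adjusted over the list alone, fry's adjusted p = 3.08e-06, adjusted p = 0.903 with an estimated correlation), Ndufb3 by 1.05 ± 0.10 and Ndufa2 by 1.01 ± 0.09. Plin4, a lipid droplet coat protein, rose by 2.23 ± 0.46 in hippocampus. Of the glucocorticoid response genes there, 7 rose and 2 fell of 16 tested (9 and 2 adjusted over the list alone, fry's adjusted p = 0.0908), with the metallothionein Mt2 at 1.30 ± 0.17 and Ddit4 at 0.56 ± 0.14. Of the hippocampal immediate early genes 0 rose and 7 fell of 20 tested (0 and 8 adjusted over the list alone, fry's adjusted p = 0.148), with Egr3 at -0.59 ± 0.07 and Egr1 at -0.996 ± 0.24. In skeletal muscle endothelial genes fell (0 rose and 9 fell of 12 tested, 0 and 11 adjusted over the list alone, fry's adjusted p = 0.00141, adjusted p = 0.903 with an estimated correlation), with the VEGF receptor Kdr at -2.05 ± 0.30, Tie1 at -1.50 ± 0.22 and Cdh5 at -1.37 ± 0.23. Smooth muscle genes fell (0 rose and 5 fell of 9 tested, 0 and 6 adjusted over the list alone, fry's adjusted p = 0.0286, adjusted p = 0.903 with an estimated correlation), with Acta2 at -1.49 ± 0.36. Zbed6 rose in muscle by 3.54 ± 0.53, from 3.92 ± 2.71 (SD, n = 5) to 45.5 ± 11.7 (SD, n = 5) CPM, and Lnpep, an aminopeptidase, by 2.49 ± 0.45. In heart Hif3a, a hypoxia-inducible factor subunit, rose by 2.33 ± 0.48. Among the genes above, adjusted p reached at most 0.0118.

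Over 7 tissues 9476 gene tests passed for exenatide in ST, 4837 up and 4639 down. Hippocampus gave 5311, and counts of the other tissues moved by over 1.5 times with 1 or more animals left out. Adipose tissue gave 0 with edgeR (1834 at an unadjusted p under 0.05) and 182 with DESeq2. In frontal cortex the glucocorticoid-induced co-chaperone Fkbp5, named after its value was seen, changed by 0.57 ± 0.09. Fry called 5 of 295 lists (2 up and 3 down) and camera with an estimated correlation 0 (14 at an unadjusted p under 0.05).

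Rapamycin was compared with the same aged ST controls (n = 5 and 5, white blood cells 4 and 5). Cytosolic ribosomal proteins rose in hippocampus (40 rose and 0 fell of 40 tested, 40 and 0 adjusted over the list alone, fry's adjusted p = 5.11e-10, adjusted p = 0.322 with an estimated correlation), Rpl37 by 1.22 ± 0.08 and Rpl30 by 1.10 ± 0.08. In hippocampus excitatory and inhibitory neuron genes rose as well (6 rose and 0 fell of 16 tested, 6 and 0 adjusted over the list alone, fry's adjusted p = 0.0201, adjusted p = 0.839 with an estimated correlation), Nrgn by 0.47 ± 0.08. Cytosolic ribosomal proteins also rose in frontal cortex (38 rose and 0 fell of 40 tested, 39 and 0 adjusted over the list alone, fry's adjusted p = 0.00135, adjusted p = 0.522 with an estimated correlation). Homeostatic microglia genes fell in hippocampus (0 rose and 10 fell of 12 tested, 0 and 10 adjusted over the list alone, fry's adjusted p = 0.00105, adjusted p = 0.679 with an estimated correlation), with Gpr34 at -0.44 ± 0.09. Hippocampal cholesterol synthesis genes fell (1 rose and 12 fell of 21 tested, 1 and 15 adjusted over the list alone, fry's adjusted p = 0.00147, adjusted p = 0.801 with an estimated correlation), such as Sqle (-0.50 ± 0.08) and Msmo1 (-0.51 ± 0.07). The macrophage gene Gpnmb fell in hippocampus (-0.80 ± 0.15) and muscle (-1.38 ± 0.29), and Adgre1 in hippocampus (-0.79 ± 0.13) and heart (-1.74 ± 0.30). In white blood cells Jchain fell by 4.27 ± 0.66, from 61 ± 56.6 (SD, n = 5) to 3.14 ± 1.63 (SD, n = 4) CPM; without E13 the aged control mean was 37 CPM and the log2 fold change -3.548. Unfolded protein and integrated stress response genes fell there (0 rose and 9 fell of 24 tested, 0 and 9 adjusted over the list alone, fry's adjusted p = 0.00192, adjusted p = 0.522 with an estimated correlation), with Sdf2l1 at -1.93 ± 0.36 and Pdia6 at -1.31 ± 0.22. The translation factor gene Eif3f rose in frontal cortex (0.42 ± 0.05) and heart (0.58 ± 0.13), and the heat shock factor Hsf4 rose in heart (1.40 ± 0.18), frontal cortex (0.55 ± 0.12) and hippocampus (0.40 ± 0.10). In heart the thioesterase Acot1 rose by 1.05 ± 0.20 and Lipe by 1.17 ± 0.22. The largest adjusted p among these genes was 0.0046.

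Rapamycin gave 15658 calls over 7 tissues, 7961 up and 7697 down, and 9421 with animal E6 left out. Hippocampus gave 5121, and counts of the other tissues moved by over 1.5 times with 1 or more animals left out; adipose tissue gave 1, the acyltransferase Mogat2 (-6.00 ± 0.97), named after its value was seen. That call was lost, with adjusted p from 0.0522 to 0.169, without E10, E13, E22, E28, E32 (log2 fold change -5.323), E36 or E6. Fry called 34 of 295 lists (11 up and 23 down) and camera with an estimated correlation 0 (17 at an unadjusted p under 0.05). Effects of exenatide and rapamycin share the aged controls, so they were compared with simulated groups without effects. The median r across genes was 0.62 over 7 tissues, 0.50 in the simulated groups and 0.37 with the aged controls split. In hippocampus r was 0.84 (0.56 split) and the covariance 0.11, against 0.02 simulated; in adipose tissue r was -0.07 (-0.23 split). Genes called in both rose together 2860 times (520 for independent lists, n1 × n2 / N), fell together 2564 times (466) and went opposite ways 11 times (979). That reference leaves out the shared controls, so the excess is not a count of shared effects. Mogat2 lost its call with the length and GC trend removed and with only the conditions compared.

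Glp1r, the knockdown target, was read first in the ST libraries, which included no hypothalamus, so these values do not check the knockdown there. In hippocampus Glp1r was at 1.05 ± 0.874 CPM (SD, n = 5) in aged controls and 0.663 ± 0.528 with the knockdown, and in frontal cortex at 0.902 ± 0.984 and 0.395 ± 0.271; no difference passed the test (adjusted p = 0.555 and 0.26). The aged control means were 0.693 CPM without E32 (hippocampus) and 0.463 CPM without E13 (frontal cortex). In LT lung, the tissue with the highest level, it was at 38.1 ± 10.5 CPM (SD, n = 8) in young controls, 26.8 ± 9.06 in aged controls and 27.7 ± 13.1 after exenatide.

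Knockdown mice were compared with aged ST controls (n = 5 and 5). In hippocampus the knockdown group had more Lnpep (2.44 ± 0.49), Zbed6 (1.95 ± 0.46), Herc1 (0.47 ± 0.09), Vps13d (0.60 ± 0.11), Ranbp2 (0.52 ± 0.08) and Bod1l (0.45 ± 0.09). With the trend on length and GC removed the last 4 stayed called, with smaller log2 fold changes. Hippocampus gave 925 calls, and another split of the ST animals gave 3180 there. In muscle Zbed6 rose by 3.20 ± 0.52, the stress gene Sesn3 by 1.45 ± 0.28 and the histone demethylase Kdm5a by 0.72 ± 0.12, and Fmod, the matrix proteoglycan fibromodulin, fell (-2.23 ± 0.50). Of the endothelial genes in muscle 0 rose and 7 fell of 12 tested (0 and 11 adjusted over the list alone, fry's adjusted p = 0.148), with Cdh5 at -1.03 ± 0.23. For these genes adjusted p was at most 0.0165. The comparison gave 3871 calls over 7 tissues (2241 up and 1630 down, 57.9% up); leaving out E20, E23, E30, E35 or E8 gave 2511, 1090, 1326, 1422 or 2346. Adipose tissue and colon gave 0 with edgeR (505 and 253 at an unadjusted p under 0.05) and 2 and 0 with DESeq2. The sum was 1780 with the trend on length and GC removed (1240 up, 69.7%), 2044 with no filter on low counts and 6472 with DESeq2, and fry called 0 of 295 lists (31 at an unadjusted p under 0.05; camera 0).

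Exenatide was also compared within knockdown mice (n = 5 and 5). In hippocampus genes of oxidative phosphorylation, nuclear-encoded, rose (32 rose and 0 fell of 38 tested, 34 and 1 adjusted over the list alone, fry's adjusted p = 6.61e-07, adjusted p = 0.627 with an estimated correlation), Cox5b by 1.52 ± 0.12 and Ndufb3 by 1.18 ± 0.10. Cytosolic ribosomal proteins rose too (30 rose and 0 fell of 40 tested, 31 and 0 adjusted over the list alone, fry's adjusted p = 6.98e-06, adjusted p = 0.847 with an estimated correlation), Rps29 by 1.16 ± 0.11. Excitatory and inhibitory neuron genes rose with them (6 rose and 0 fell of 16 tested, 8 and 1 adjusted over the list alone, fry's adjusted p = 0.00852, adjusted p = 0.847 with an estimated correlation), Nrgn by 0.43 ± 0.08. Glucocorticoid response genes rose as well (6 rose and 0 fell of 16 tested, 6 and 0 adjusted over the list alone, fry's adjusted p = 0.0195, adjusted p = 0.847 with an estimated correlation), Mt2 by 1.36 ± 0.17 and Ddit4 by 0.64 ± 0.14, and the lectin-like gene Clec2d rose by 1.94 ± 0.30. Adjusted p was 7.54e-04 or lower for each of these genes. Hippocampus gave 5810 of the 5848 calls over 7 tissues (3021 up and 2827 down in all), and 8922 were called with DESeq2. White blood cells, frontal cortex and muscle gave 0 with edgeR (2797, 1555 and 1976 at an unadjusted p under 0.05) and 214, 1 and 192 with DESeq2. Fry called 10 of 295 lists (4 up and 6 down) and camera with an estimated correlation 0 (11 at an unadjusted p under 0.05). With the trend on transcript length and GC content removed, the call of Nrgn (hippocampus) was lost.

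The test of the difference between the 2 exenatide effects, with and without knockdown, passed for 2856 genes, 1388 with a higher and 1468 with a lower effect under knockdown, 2843 of them in muscle, 8 in hippocampus and 5 in heart. In muscle the effect on endothelial genes was higher under knockdown (11 rose and 0 fell of 12 tested, 11 and 0 adjusted over the list alone, fry's adjusted p = 0.00152, adjusted p = 0.882 with an estimated correlation), with Cdh5 at 2.13 ± 0.33, Tie1 at 2.28 ± 0.31 and Flt1 at 2.23 ± 0.37. So was the effect on smooth muscle genes (5 rose and 0 fell of 9 tested, 6 and 0 adjusted over the list alone, fry's adjusted p = 0.0382, adjusted p = 0.882 with an estimated correlation), with Myh11 at 1.997 ± 0.46 and Acta2 at 1.93 ± 0.50. The difference for Fmod was 4.96 ± 0.72. Its mean muscle level was 38.6 CPM in aged controls and 4.499 CPM with exenatide alone, against 8.23 CPM with the knockdown alone and 29.7 ± 25.8 CPM (SD) with exenatide and knockdown (n = 5 each). Without E33 the last mean was 18.7 CPM and the difference 4.289. Among the genes above, adjusted p reached at most 0.00737. The sum was 4676 without animal E13 and 1661 with the trend on length and GC removed. Adipose tissue, white blood cells, colon and frontal cortex gave 0 with edgeR (743, 1314, 403 and 2950 at an unadjusted p under 0.05) and 0, 0, 0 and 11 with DESeq2. Across genes, r between the 2 exenatide effects, which share no library, was 0.62 in adipose tissue, 0.49 in hippocampus, 0.47 in colon, 0.40 in white blood cells, 0.06 in frontal cortex, -0.06 in heart and -0.37 in muscle, and simulated groups without effects gave a median of -3.37e-04. The error of r, from leaving out each library in turn, had a median of 0.19. Simulated genes varied independently of each other, so this reference does not show how far r moves by chance between real genes. In adipose tissue edgeR called 0 genes for exenatide without knockdown and 4 within knockdown. Genes called in both rose together 1812 times (424 for independent lists), fell together 1692 times (406) and went opposite ways 17 times (831). As hippocampus held 5810 of the 5848 calls within knockdown, nearly all of this overlap lies in that tissue. There, 53.3% of the calls for exenatide without knockdown were kept with the trend on length and GC removed.

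**Figure D3:**
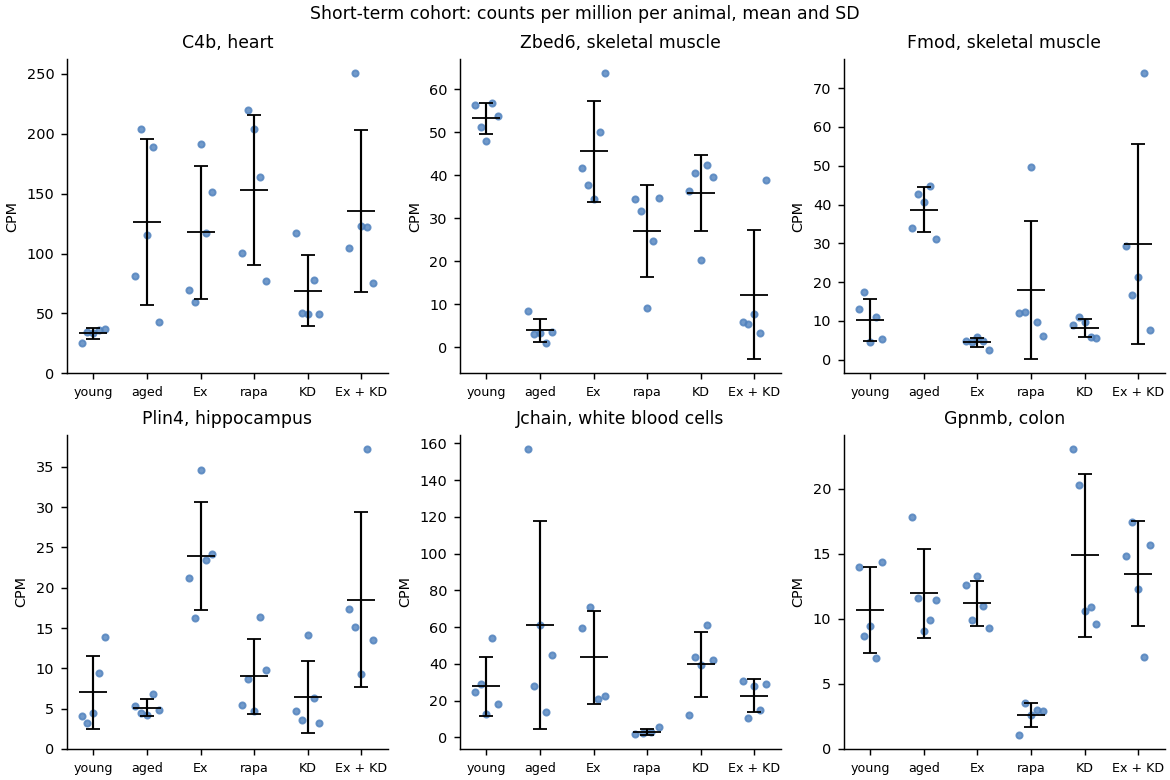
CPM of 6 genes in ST tissues, 1 point per animal with the group mean and SD, in the 6 conditions. Muscle Zbed6 was at 3.92 CPM in aged controls and between 26.95 and 53.18 CPM in the other groups, except exenatide with knockdown (12.2 CPM, and 5.56 CPM without E34). White blood cell Jchain was at 61.0 CPM in aged controls (37 CPM without E13) and 3.14 CPM after rapamycin.

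**Figure D4:**
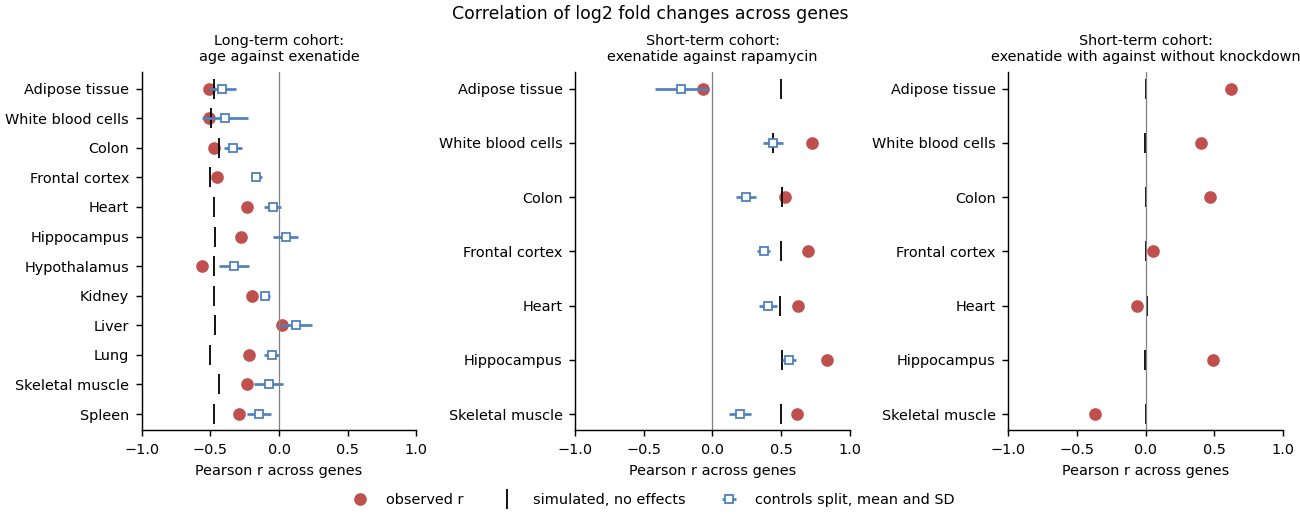
Pearson's r across genes per tissue between LT age and exenatide effects, ST exenatide and rapamycin effects, and ST exenatide effects with and without knockdown. Filled points give the observed r, with simulated groups without effects and, for pairs that share controls, the mean and SD with the aged controls split; hippocampus r for exenatide and rapamycin was 0.84 observed and 0.56 split.

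Scores asked whether genes of one cohort's age or exenatide effect moved as a set in another cohort, by two-sided permutation tests adjusted over tissues. The score of LT age genes in ST animals was higher in aged than young controls by 0.25 in hippocampus and 0.17 in frontal cortex (n = 5 and 5, exact permutation adjusted p = 0.0556 in both), and 0 of 7 tissues passed. At the same adjusted p, this score was higher with exenatide than in aged controls in hippocampus (by 0.1942) and lower with the knockdown in frontal cortex (-0.1113). The smallest p that the 252 arrangements of 5 against 5 animals can give is 0.00794. On its own among 7 tissues this adjusts to 0.0556, so a single tissue could not pass whatever its values. With the 200 genes of smallest p the age differences passed in hippocampus (adjusted p = 0.037) and frontal cortex (0.0278), and without E13 the exenatide difference in hippocampus did (0.0278). In LT animals, ST age genes gave 0 of 5 tissues for age and 0 of 5 for exenatide. The score of LT exenatide genes was higher in aged than in young ST controls in white blood cells (by 0.78) and heart (by 0.32; exact permutation adjusted p = 0.0198 in both). In heart this did not pass without E13, E29, E30 or E32 (0.0595 each). Exenatide under knockdown raised that score in heart (by 0.25, exact permutation adjusted p = 0.0397), but not without E12, E15, E16, E33 or E34 (0.119 to 0.198), and exenatide without knockdown passed in 0 of 5 tissues. Its difference from aged controls in white blood cells was negative (-0.639, exact permutation adjusted p = 0.0794), as was that of rapamycin (-0.612, adjusted p = 0.119). With a signature at adjusted p under 0.01, heart and white blood cells held fewer than the 20 genes needed for a score, so these results could not be repeated, and 0 tests passed in the other tissues. In YA animals neither score passed in any of 8 and 6 tissues (exact permutation).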

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

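Of the tests in this part, those of length and GC trends in ST hippocampus and muscle, of muscle depth, of libraries of low correlation, of single hippocampus libraries and of the liver genes were chosen after the results they bear on were seen. The other splits of the animals, the thinning of hippocampus libraries and the tests of the colon libraries were written down before their results were seen. Patterns below that were noticed in the data are hypotheses.

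Many gene calls in ST hippocampus and muscle followed transcript length and GC content. In hippocampus the lists of cytosolic ribosomal proteins and of oxidative phosphorylation, nuclear-encoded, fell with age and rose with exenatide and rapamycin (all against the same aged controls), while in muscle neither list passed for age or exenatide and the cytosolic ribosomal proteins rose with rapamycin (fry's adjusted p = 0.0474, adjusted p = 0.839 with an estimated correlation). Both lists also rose in hippocampus with exenatide within knockdown, which does not use these aged controls (fry's adjusted p = 6.98e-06 and 6.61e-07, in that order). That contrast is not among the calls counted next. Of its 27 named calls, 17 were kept with the length and GC trend removed. Of 22281 calls for age, exenatide and rapamycin in these tissues, 13333 were kept in the same direction with each library's length and GC trend removed, a share of 0.598, so RNA or library quality that follows length and a change of these genes in the animals cannot be told apart. For age, exenatide and rapamycin, hippocampus kept 60.9%, 53.3% and 70.8% and muscle 50.7%, 49% and 78.2%. The neuron list moved the same way in hippocampus for age and rapamycin. Among the calls lost, the median size of the log2 fold change for age went from 0.267 (standard error 0.0772) to 0.113 (0.0669) in hippocampus and from 0.427 (standard error 0.118) to 0.177 (0.106) in muscle. Depth is argued against in muscle for age and exenatide, where mean total counts differed between groups by at most 1.04 times. That ratio was not computed for rapamycin in muscle. In hippocampus it was 1.55 (age), 1.67 (exenatide) and 1.46 (rapamycin). With all hippocampus libraries thinned to 22.7 M a share of 0.859 of the calls was kept, which argues against the number of counts alone. Thinning does not remove other differences between libraries that go with depth, and these were not tested. In hippocampus no library of low correlation lay in the groups compared, so each animal of these groups was left out in turn: the lowest share of calls kept was 0.743 (age without E29; exenatide without E29 0.778), under the limit of 0.8 set for excluding a single library and over the 0.5 expected if it were the cause, so this stays open. Without libraries of low correlation a share of 0.71 was kept in muscle, where 2 of 5 aged controls (E13 and E23) were left out and the median size of the lost calls for age went from 0.613 (standard error 0.189) to 0.378 (0.185), so in muscle these 2 libraries and the groups cannot be told apart. The part kept there was 77% for age, 73.6% for exenatide and 55.4% for rapamycin.

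In exenatide-treated LT livers, genes that are higher in female than in male mouse liver rose (among them Cyp2a4, Cux2 and Cyp2b9) and genes that are higher in males fell (Mup7, Hsd3b5, Elovl3, Cyp4a12b and Cyp2d9), 9 of the 10 that could be tested among 12 listed; Cyp2d9 lost its call without the liver titled B13 (adjusted p = 0.0568), which its description names B14, Cyp4a12a was at -2.17 ± 0.60 (adjusted p = 0.0777), and Sult2a1 and Cyp2b13 were not tested. A mislabelled female liver is argued against, since Xist reached at most 0.204 CPM and Eif2s3y lay between 40.5 and 66.8 CPM in the exenatide livers. All 9 kept call and direction with the length and GC trend removed (9), and a share of 1 kept them without the 2 livers of low correlation, B36 (exenatide) and A55 (young), which argues against either as the cause, although the limit for the first of these tests was reworded after the 9 was seen, since the earlier one could not be met by 9 called genes. A hypothesis that remains is that exenatide, or its effect on food intake or body weight, may shift the sex-biased liver programme towards the female pattern; growth hormone and sex hormones were not measured in these data, so it was not tested.

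Of 6 young LT colon libraries, 2 (animals A52 and A53) held transcripts of the small intestine. Over 6 of 7 small intestine genes fixed before they were looked at (Defa24 was not in the table), the median ratio to the median of the other 4 young colons was 178 in A52 and 1070 in A53; Apoa4 was at 981 and 12500 CPM, against 0.0555 CPM. With the length and GC trend removed the lower ratio was 197, which argues against that trend. Tissue from the small intestine in these 2 samples, or a mix-up of tissues at dissection, is consistent with these values, and a biological difference between young animals was not tested. Without both libraries the LT colon gave 699 calls for age in place of 2503, and 9 of 33 named colon calls were kept. The LT colon age signature of the scores and the colon r of age against exenatide also used both libraries. No values without them are given for these.

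The real split of the animals was set against other splits of the same animals into groups of the same sizes, with all tissues of an animal kept together. For calls summed over tissues, only the real split (1) of 25 (LT) or 41 (ST) gave as many calls. This argues against chance in the grouping of animals, but no lower share was possible and none was adjusted over contrasts. The real sum, with the highest of the other splits after it, was for LT age 26891 (1893), LT exenatide 9754 (4122), ST age 16066 (3394), ST exenatide 9476 (3005), rapamycin 15658 (2207), knockdown 3871 (3401), exenatide under knockdown 5848 (3991) and the difference by knockdown 2856 (2097). For the knockdown the margin is small, so chance stays open. Without E20, E23, E30, E35 or E8, among others, the sum lay below the 3401 of another split of all animals. The splits were not repeated without these animals. In some single tissues with calls, at least 1 other split gave as many or more, so chance is not excluded by this test for the counts there. These were LT age in hippocampus (71 real, 1893 highest other), LT exenatide in adipose tissue (3174, 4122) and frontal cortex (17, 659), ST age in colon (4, 6), ST exenatide in white blood cells (1011, 1742) and frontal cortex (5, 280), and rapamycin in colon (71, 102). For the knockdown they were white blood cells (1211, 2685), hippocampus (925, 3180), muscle (572, 2425) and heart (11, 42). Exenatide under knockdown in adipose tissue (4, 2409) and heart (4, 12) and the difference by knockdown in heart (5, 10) were the others. In YA animals 2 of 41 splits, the real one included, gave as many calls as the real 798. The other gave 1957, in frontal cortex, where the real split gave 0, and in colon, with 796 of the 798, no other split gave a call (highest 0).

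The effect of exenatide differed with and without knockdown, by the test of the difference, in 2843 genes of skeletal muscle, 8 genes of hippocampus and 5 genes of heart. The heart genes, named after their values were seen, were Ccdc84 (-0.99 ± 0.19), Sfxn2 (-1.10 ± 0.21), Gm30093 (-3.54 ± 0.61), LOC102631979 (3.01 ± 0.41) and LOC118568621 (3.12 ± 0.58). Ccdc84 and Sfxn2 were not called without the filter on low counts. With each animal left out, the count ran from 1 (E12) to 157 (E21) in heart and from 0 (E12) to 197 (E21) in hippocampus, and moved by over 1.5 times with 28 and 25 of 30 animals; in muscle it was 4671 without E13.

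In 22 of 209 groups of 4 to 9 animals 1 value lay far from the others by Dixon's test, which chance gives in about 1 of 20 groups. For total counts, 12 of 94 groups held such a library. In adipose tissue these were E8 (knockdown) at 53.9 M, E16 (exenatide with knockdown) at 42.5, A34 (YA exenatide) at 34.1, E30 (ST aged control) at 32.9, B37 (LT aged control) at 31.9 and A58 (LT young control) at 25.3 M. In white blood cells they were E20 (knockdown) at 50.2, E15 (exenatide with knockdown) at 28.3, B14 (LT exenatide) at 28.2 and A44 (ST young control) at 14.7 M. The others were A57 in LT young hypothalamus at 30.9 M and A55 in LT young kidney at 27 M. The score of LT age genes stood apart in ST adipose tissue for E23 (aged control, 0.255, others -0.588 to -0.366) and E8 (knockdown, -0.00682, others -0.632 to -0.456). It also stood apart in hippocampus for E33 (exenatide with knockdown, 2.33, others 2.06 to 2.11) and the YA control A87 (1.73, others 1.49 to 1.59), and in muscle for E13 (aged control, 0.0858, others at least 0.469). The score of LT exenatide genes stood apart in adipose tissue for E19 (ST exenatide, -0.154) and the YA control A81 (-0.882), in colon for E15 (exenatide with knockdown, 0.807) and A79 (YA exenatide, -0.981), and in heart for the YA control A41 (1.27).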

How the results depend on the processing

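The alternatives without length and GC trends, libraries of low correlation or 2 young colon libraries were chosen after the data were seen. No paired analysis was possible because no animal appears in 2 conditions. Gene lists were not refitted without each animal. Where a value below moved, the cause was not tested, except that batch 3 alone holds fewer libraries.

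Over all alternatives 292 sums of gene calls were within 1.5 times of the value reported and 21 moved further. For single tissues 1843 counts were within 1.5 times and 611 moved further. With DESeq2's size factors in edgeR, each sum of gene calls stayed within 1.5 times. With batch 3 alone, the sums were 3509 (LT age) and 3310 (LT exenatide). With the length and GC trend removed they were 3295 (LT exenatide), 1661 (difference of exenatide effects by knockdown) and 1780 (knockdown). With DESeq2 they were 15582 (LT exenatide), 8922 (exenatide within knockdown), 6472 (knockdown) and 1449 (YA). With no filter on low counts the knockdown gave 2044, and without the libraries of low correlation the difference by knockdown gave 4356. With each animal left out in turn the sums ran from 21847 to 28794 (LT age), 6266 to 12233 (LT exenatide), 461 to 1013 (YA), 12280 to 17273 (ST age), 6889 to 10355 (ST exenatide), 9421 to 16718 (rapamycin), 1090 to 5258 (knockdown), 5096 to 7459 (exenatide within knockdown) and 2306 to 4676 (difference by knockdown). The lowest and highest for the knockdown were without E23 and E21, and for LT exenatide without B14 and B13.

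Camera with an estimated correlation called 0 lists for LT age, LT exenatide, ST age, ST exenatide, rapamycin, exenatide within knockdown and the difference by knockdown, where fry called 126, 13, 32, 5, 34, 10 and 2. With a preset correlation it called 110 (LT exenatide), 58 (YA), 84 (ST age), 70 (ST exenatide), 77 (rapamycin), 69 (knockdown), 77 (exenatide within knockdown) and 73 (difference by knockdown). With DESeq2's size factors fry called 21 lists for rapamycin. Counts of tissues in which a score passed moved as follows: the LT age score in ST animals passed in 3 tests with the 200 genes of smallest p, and in 0 to 2 with an animal left out. The ST age score in LT animals passed in 2 with 200 genes and in 0 to 1 with an animal left out, the LT age score in YA animals in 0 to 1, and the exenatide score in 0 with a signature at adjusted p under 0.01, at which heart and white blood cells had too few genes for a score. With the aged controls split, the median r was -0.1242 (LT age against exenatide) and 0.3721 (exenatide against rapamycin).

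Of the gene values under other settings, 38069 kept their direction and were called or not called as before, 3238 lost a call, 426 gained one, 49 changed sign without a call in either fit, and 9 changed sign with a call. The log2 fold changes below are those 9 and the ranges they belong to. With the length and GC trend removed: Cck, ST exenatide under knockdown, Hippocampus (-0.06442) and Fbxl20, ST exenatide, Circulating_WBCs (-0.01912). Guca2b, LT age, Colon was at 0.1473 without libraries of low correlation and at 0.4573 without the 2 colon libraries. With batch 3 alone: Kcnj13, LT age, Colon (0.2599) and Retnlg, LT age, Colon (-0.03432). With an animal left out: Gbp10, ST exenatide, Skeletal_muscle from -1.276 (E31) to 6.121 (E23), Gbp10, ST exenatide by knockdown, Skeletal_muscle from -6.551 (E23) to 0.8307 (E31), and Myh4, ST exenatide, Heart from -3.823 (E7) to 9.237 (E13). At the depth of ST hippocampus, edgeR recovered 77.8% of genes changed 2-fold in simulated data and 99% of those changed 4-fold, and recovery by depth or level of a gene was not tested.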

Other observations

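Gene list tests here were planned, and the lists described chosen after results were seen. With age, circadian clock genes of LT adipose tissue changed, mostly downward (2 rose and 9 fell of 18 tested, 2 and 9 adjusted over the list alone, fry's adjusted p = 0.00517, adjusted p = 0.624 with an estimated correlation), such as Dbp (-1.53 ± 0.23), Ciart (-1.14 ± 0.24) and Nr1d1 (-1.11 ± 0.27). The cell cycle inhibitor Cdkn2a, a common marker of senescent cells, rose with age in LT liver (2.25 ± 0.45) and spleen (2.38 ± 0.29) as well as in heart. Aged LT muscle also held more antibody transcripts (B and plasma cell markers, 5 rose and 0 fell of 7 tested, 6 and 0 adjusted over the list alone, fry's adjusted p = 2.98e-04, adjusted p = 0.317 with an estimated correlation), Ighg2c by 3.90 ± 0.36. Erythroid transcripts of LT adipose tissue fell with age (0 rose and 5 fell of 5 tested, 0 and 5 adjusted over the list alone, fry's adjusted p = 0.00456, adjusted p = 0.612 with an estimated correlation), with Hbb-bt at -2.16 ± 0.49. The largest adjusted p among these genes was 0.00453.

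In the ST cohort, neutrophil markers rose with age in heart (5 rose and 0 fell of 8 tested, 6 and 0 adjusted over the list alone, fry's adjusted p = 0.0134, adjusted p = 0.651 with an estimated correlation), S100a8 by 2.31 ± 0.63 and S100a9 by 2.32 ± 0.61 (2.976 and 2.995 without A46). Genes of the list fatty acid oxidation and PPAR alpha targets fell there (0 rose and 9 fell of 23 tested, 0 and 10 adjusted over the list alone, fry's adjusted p = 0.0355, adjusted p = 0.651 with an estimated correlation), with Cpt2 at -0.44 ± 0.10 and Hadh at -0.51 ± 0.10. Rapamycin raised genes of oxidative phosphorylation, nuclear-encoded, in hippocampus (26 rose and 0 fell of 38 tested, 27 and 0 adjusted over the list alone, fry's adjusted p = 4.21e-05, adjusted p = 0.679 with an estimated correlation), Ndufa5 by 0.92 ± 0.07. It lowered fatty acid synthesis genes there (1 rose and 8 fell of 17 tested, 1 and 8 adjusted over the list alone, fry's adjusted p = 8.89e-04, adjusted p = 0.633 with an estimated correlation), with Elovl6 at -0.41 ± 0.06 and Scd1 at -0.40 ± 0.07. Homeostatic microglia genes, which other macrophages share, fell with rapamycin in heart (0 rose and 7 fell of 12 tested, 0 and 8 adjusted over the list alone, fry's adjusted p = 0.028, adjusted p = 0.839 with an estimated correlation), with Gpr34 at -1.54 ± 0.27 and Csf1r at -0.85 ± 0.21. For these genes adjusted p was at most 0.0123. Library quality is not excluded as a cause for rapamycin in hippocampus (above).

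In adipose tissue of ST mice with exenatide and knockdown, 5 lists were lower than with the knockdown alone by fry, each with 0 genes called: fatty acid oxidation and PPAR alpha targets (0 rose and 0 fell of 25 tested, 0 and 10 adjusted over the list alone, fry's adjusted p = 0.0059, adjusted p = 0.627 with an estimated correlation), white adipocyte (0 rose and 0 fell of 17 tested, 0 and 7 adjusted over the list alone, fry's adjusted p = 0.0398, adjusted p = 0.847 with an estimated correlation), thermogenic adipocyte (0 rose and 0 fell of 10 tested, 0 and 3 adjusted over the list alone, fry's adjusted p = 0.0059, adjusted p = 0.627 with an estimated correlation), cardiomyocyte stress (0 rose and 0 fell of 7 tested, 0 and 4 adjusted over the list alone, fry's adjusted p = 0.00852, adjusted p = 0.627 with an estimated correlation) and skeletal muscle contamination (0 rose and 0 fell of 11 tested, 0 and 3 adjusted over the list alone, fry's adjusted p = 0.00852, adjusted p = 0.717 with an estimated correlation). In that group 4 of the 5 libraries were among the libraries of low correlation with their tissue.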
